A study of Mus musculus with 12 samples.

How the data were processed

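RNA of the chromatin input and of the HP1γ immunoprecipitate was sequenced in 12 libraries of mouse fibroblast-derived cells that re-express HP1γ, as 65 bp single-end reads from directional total RNA libraries, per the labels' protocols. The labels give 4 groups of 3 biological replicates. The design text also mentions cells without HP1γ, which are not analysed here. The submitters' processing notes name cutadapt 1.11, STAR 2.5.0a, featureCounts 1.4.6-p3 from Subread, MACS2 2.1.0, deepTools and the build mm9, without their roles or order. The settings of peak calling and filtering are not given in the sources used here.

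The deposited data are 2 peak lists in MACS2's narrowPeak layout, 1 for untreated and 1 for PMA-treated cells, each for IP against input. They hold no strand. Peaks were called per replicate and then joined, as the deposited lists show: each region lists its member peaks by replicate and number, no region has fewer than 3, and the score and the summit offset, multiplied by the number of member peaks, come out within 0.001 of a whole number in all 10013 untreated and 2609 PMA regions. As deposited, 30.9% and 33.9% of the scores and 31.3% and 31.2% of the offsets are whole. The deposited fold enrichment, a ratio of IP over input, the −log10 p and −log10 q values and the score (close to 10 times −log10 p) are therefore read as means that the authors took over member peaks; for fold, p and q this reading is carried over from the score and offset and was not tested. The mean offset gives no summit position in the joined region, so the planned comparison of summits was replaced by one of region centres. A mean −log10 q below −log10 of 0.05 was found in 3.34% of untreated and 2.45% of PMA regions. Because a region must gather 3 member peaks, the lists depend on how many replicates were joined and on how often a caller split an enriched stretch. The member peaks of the PMA list bear the numbers of replicates 2 and 3 only. Member peak numbers rise along the genome within each replicate, so the highest number gives the least number of peaks called: 87348, 40773 and 33450 in untreated replicates 1, 2 and 3, and 49502 and 92243 in PMA replicates 2 and 3. Read depth is unknown for every library.

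The coordinates reach beyond the last gene of GRCm38 on 7 chromosomes, with 118 regions past it and 62 of these on chromosome 7. The gene tables at hand are of that other build, so they were not used to name genes, and the planned tests on genes, gene parts, gene lists and sequence were not run. The lists hold no values per library, so the planned model over the 12 libraries was not run either. Start coordinates are printed 1-based.

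From the lists, region numbers, widths, fold enrichments and chromosome shares were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. No rows of a list overlapped, so none were merged. Shares carry exact Clopper-Pearson 95% intervals and medians carry order-statistic intervals. These cover counting error only, and regions in a group are not independent. Partners are regions of the other list that overlap by at least 1 bp. The overlap was set against 10000 circular shifts of a list along its chromosomes and 10000 local moves of each region by 5 to 50 kb, and clustering against 10000 uniform placements. Chromosome lengths were replaced by the span that both lists cover. Fold enrichments of shared and unshared regions were compared within each list by permutation. These tests compare positions within or between the lists, and say nothing of the variation between cultures. Regions named in the text are, per list, the 10 highest by fold, the 5 highest by −log10 q, the 5 strongest without a partner and the 5 fullest 1 Mb windows, and the 10 strongest shared regions, of which the first 3 are given. The rule, the tests and most alternatives were fixed before the data were examined. Reduced untreated lists, with at least 3 member peaks from 2 of the replicates, and the width of untreated regions with member peaks from only 2 replicates, were added after seeing the member peaks. Reduced lists keep the deposited region bounds, folds and q values, because positions and values of single member peaks are not given. Overlap over quartiles is also given as a ratio to the mean share of locally moved regions.

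The code was tested on simulated lists. A list of 2603 regions with 30% of them taken from the untreated list gave a share of 30.2%, and 4 of 100 random lists had an overlap p under 0.05 by circular shifts. The random lists were placed uniformly, without the grouping of the real lists, so the error rate for grouped lists was not checked. Local moves were not tested on simulated lists. For 3 simulated replicates giving 15182 joined regions, reduced lists taken from member names held 5823 to 5846 regions, where joining 2 replicates alone gave 5340 to 5375. In this simulation the reduced lists thus overstated the number of such regions somewhat. The simulated replicates had equal calling rates, unlike the untreated replicates, whose reduced lists kept 15.0% to 23.6% of regions. The bias in the data may therefore differ. Alternatives covered stricter q and fold limits, merging within 1 kb, other overlap criteria, equal list lengths, other shifts, distances and windows, and leaving out each untreated replicate.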

Results

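Chromatin-associated RNA recovered with HP1γ was measured by RNAchIP-seq in mouse fibroblasts, with and without a short phorbol ester treatment. HP1γ (the product of Cbx3) is a chromodomain protein that binds methylated histone H3 in chromatin. The cells are derived from mouse embryonic fibroblasts that lack HP1γ and had HP1γ expression restored. In RNAchIP, lightly crosslinked nuclei are treated with DNase and sonicated, HP1γ is immunoprecipitated from the solubilised chromatin, and the RNA that comes with it is sequenced next to the RNA of the chromatin input. PMA, an activator of protein kinase C, was added at 100 nM for 30 min as the stress. The 12 libraries form 4 groups of 3 replicates: input and HP1γ immunoprecipitate (IP), each from untreated and from PMA-treated cells. None is a mock IP or an IP from cells without HP1γ, so enrichment over input cannot tell HP1γ association from unspecific recovery of RNA. The data analysed here are 2 lists of regions enriched in IP over input, 1 per condition. Neither list gives values or read depths per library, so depth is unknown, there is no replicate error for any region, and the comparisons below are between 2 lists and not between replicated treatments. Coordinates are in mm9, the build named in the submitters' processing notes. No annotation of that build was used, so regions are identified by position and no gene, exon, intron or UTR is assigned to them.

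The untreated list held 10013 regions of RNA enriched in the HP1γ IP, on all 19 autosomes and the X chromosome, and the PMA list held 2609. The untreated list was 3.84 times as long, and covered 5.93 Mb against 2.29 Mb. Untreated regions were narrower, with a median width of 528 bp (interquartile range 408 to 687) against 780 bp (621 to 1032) after PMA. The median fold enrichment of IP over input was 3.65 (95% interval of the median 3.62 to 3.68) in untreated cells and 3.50 (3.46 to 3.53) after PMA. In the untreated lists without replicate 1, 2 or 3, described below, it was 3.46, 3.65 and 3.70, on both sides of the PMA value. These lists keep the deposited folds, which still average peaks of the replicate left out. Their medians therefore reflect which regions remain, not folds measured without that replicate. Fold enrichments here are the authors' own values per region, averaged over the peaks joined in it. The highest values were 12.5 and 10.2.

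The lists were not built from equal numbers of replicates. Each region carries the names of the peaks joined in it, at least 3 in either list. In the untreated list these came from all 3 replicates, and 9202 regions (91.9%) had a member peak in each of them. In the PMA list they came from replicates 2 and 3 only, and no member peak of replicate 1 was present. A PMA region therefore had at least 2 member peaks from 1 of its replicates. The untreated list held 7003 regions with exactly 1 member peak per replicate, and a region called once in each replicate cannot reach 3 member peaks from 2 replicates. When member peaks of 1 untreated replicate were left out and at least 3 were still required, 1505 untreated regions remained without replicate 1, 1988 without replicate 2 and 2367 without replicate 3. The PMA list was 1.10 to 1.73 times as long as these reduced lists, so the direction of the difference in number turned. This is no comparison at equal numbers of called peaks. At least 87348, 40773 and 33450 peaks were called in untreated replicates 1, 2 and 3, and 49502 and 92243 in PMA replicates 2 and 3. The reduced lists covered 1.42, 1.76 and 2.03 Mb, so the direction turned for coverage too. Their median widths were 826, 781.5 and 746 bp, but these regions keep the bounds joined over all 3 replicates, as positions of member peaks are not in the lists, so these are not widths of regions joined from 2. The 811 untreated regions with member peaks from only 2 replicates had a median width of 586 bp (571 to 601). The difference in width is therefore not settled by the reduced lists.

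**Figure D1:**
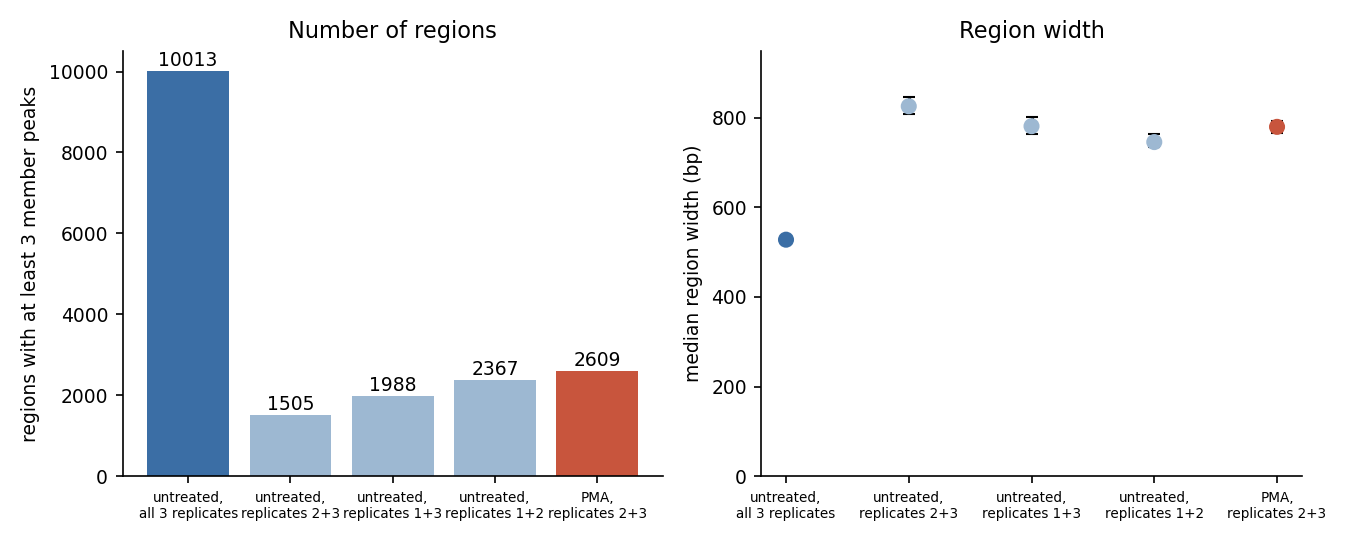
Left, the number of regions with at least 3 member peaks in the untreated list, in the untreated list reduced to each pair of replicates, and in the PMA list. Right, the median region width in bp, with bars for the 95% interval of the median; regions of the reduced lists keep bounds joined over all 3 replicates, so their widths are not compared with that of the PMA list. The full untreated list stands apart at 10013 regions and 528 bp, while the reduced lists (1505 to 2367 regions) lie near the 2609 regions of the PMA list.

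The 10 strongest untreated regions lay on 7 chromosomes and were 216 to 1155 bp wide. A 216 bp region on chromosome 6 (8727938 to 8728153) had the highest fold enrichment, 12.5, followed by a 448 bp region on chromosome 3 (122204219 to 122204666) at 11.3, a 241 bp region on chromosome 11 (103273773 to 103274013) and a 683 bp region on chromosome 17 (22873486 to 22874168), both at 10.2. The other 6 of the 10 highest were on chromosomes 5, 6, 10, 16 and 17, with folds of 8.96 to 9.80, and included a pair of neighbouring regions on chromosome 17 (26328250 to 26329257 and 26329348 to 26330502). By q value, the first was a 780 bp region on chromosome 16 (32992002 to 32992781), with a mean −log10 q of 29.1 and a fold of 7.06. Of the 10 regions with the highest fold, 2 overlapped a PMA region: chromosome 10 (75123434 to 75124263), at 9.26 in the untreated and 6.33 in the PMA list, and the first of the chromosome 17 pair, at 8.96 and 6.21. The 5 strongest regions with no PMA partner were the first 5 by fold (9.80 to 12.5). All 10 had 3 member peaks, 1 from each replicate.

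After PMA, the strongest region was on chromosome 8 (127951269 to 127952167), with a fold of 10.2 against 7.77 for its untreated partner. It was followed by regions on chromosome 7 (52074894 to 52076235), at 9.12 against 6.25, and chromosome 19 (24343382 to 24344405), at 9.07 against 4.78. A region on chromosome 5 (101092980 to 101094064) had the highest −log10 q of the list, 33.3, with a fold of 7.93 against 7.04. All 10 PMA regions with the highest fold (7.32 to 10.2) and all 5 with the highest −log10 q had an untreated partner. The strongest shared regions, ranked by the smaller of their folds, were on chromosome 14 (76298579 to 76299775 in the PMA list), at 8.37 after PMA and 7.80 untreated, the chromosome 8 region above, and chromosome 4 (151638101 to 151639150), at 7.33 after PMA and 8.08 untreated. The strongest PMA regions with no untreated partner had lower folds, of 6.23 to 6.96, and lay on chromosome 13 (93382650 to 93383608), chromosome 10 (56640546 to 56641242), chromosome 17 (5423592 to 5424239), chromosome 4 (145752538 to 145753221) and chromosome 14 (12735187 to 12735913). With 1 list per condition, no test of a change at a single region was possible.

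More PMA regions lay at positions of the untreated list than random placement gave. Of the 2609 PMA regions, 1431 overlapped an untreated region by at least 1 bp, or 54.8% (exact 95% interval 52.9 to 56.8, which covers counting error only). Circular shifts of the PMA list along each chromosome gave a mean of 0.623% and at most 5.33% over 10000 shifts (permutation of positions, one-sided p = 0.0001, the smallest these can give). Moving each PMA region by 5 to 50 kb, which keeps it in its neighbourhood, gave a mean of 7.0% and at most 8.62% (permutation of positions, one-sided p = 0.0001, again the smallest), so the overlap was 7.83 times that of moved regions. Within 10 kb of an untreated region lay 82.7% of PMA regions, and 180 were more than 50 kb from any. In the other direction, 1555 of 10013 untreated regions (15.5%, 14.8 to 16.3) overlapped a PMA region, against a mean of 0.168% in circular shifts. For untreated regions with at least 3 member peaks from 2 replicates, this share was 27.9% to 34.1%, while 19.7% to 25.03% of PMA regions overlapped one of these reduced lists. The fold enrichments of shared regions were correlated across the 1431 PMA regions and their strongest partners (Pearson r = 0.64, Spearman rho = 0.63), and regions are not independent replicates.

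The share of regions with a partner was also compared over quartiles of strength. In the untreated list, shared regions had a median fold of 3.63 and unshared regions 3.65, a difference within chance (permutation test within the list, 100000 resamples, two-sided p = 0.494). The shared portion was 14.6% in the lowest and 14.7% in the highest quartile by fold, where locally moved regions gave 2.76% and 1.47%, so the overlap went from 5.28 to 10.0 times that of moved regions. It went from 6.75% in the narrowest to 32.6% in the widest quartile, and from 10.8% to 19.6% over the quartiles of −log10 q, but moved regions also gave more, 1.20% and 3.42% by width and 1.41% and 2.74% by −log10 q. The overlap was thus 5.60 and 9.52 times that of moved regions by width, and 7.69 and 7.17 times by −log10 q, with no rise. In the PMA list, shared regions had a higher median fold than unshared ones, 3.56 against 3.43 (permutation test, two-sided p = 7.0e-05), but this difference did not hold against any of the 3 reduced untreated lists, where the p values were 0.0629 to 0.364 in the same test with 20000 resamples. By −log10 q, 25.6% of PMA regions in the lowest quartile and 86.5% in the highest had an untreated partner, 5.23 and 9.20 times the share of moved regions. By fold the shares were 53.0%, 49.4%, 50.5% and 66.6% from the lowest to the highest quartile, while those of moved regions went from 9.65% down to 5.66%. By width, the shares were 26.5% in the narrowest and 82.8% in the widest quartile, and those of moved regions 3.95% and 11.9%, so the ratio was 6.70 and 6.95 at the ends.

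**Figure D2:**
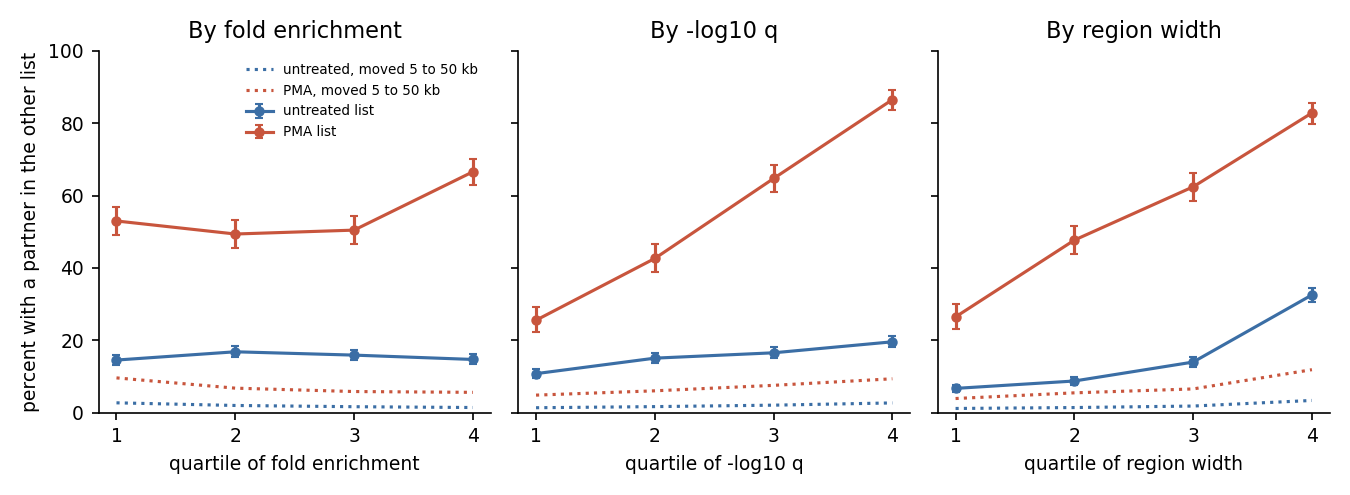
Percent of the regions of each list that overlap a region of the other list, by quartile of fold enrichment, −log10 q and region width (1 lowest, 4 highest). Points carry exact 95% binomial intervals and dotted lines give the mean after moving regions by 5 to 50 kb. The share in the PMA list goes from 25.6% to 86.5% over −log10 q, and that of moved regions from 4.89% to 9.40%.

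Regions enriched in the IP were spread unevenly over chromosomes, and on the 19 autosomes the shares in the lists had overlapping 95% intervals. Chromosome 10 held the most, with 782 untreated regions (7.81%, 7.29 to 8.35) and 220 PMA regions (8.43%, 7.39 to 9.57). Per Mb of the span covered by the lists, chromosomes 17 and 10 were the densest in untreated cells, at 6.76 and 6.17 regions, and chromosomes 10 and 17 after PMA, at 1.73 and 1.72. The autosomes together held 4.13 and 1.08 regions per Mb. The X chromosome was the sparsest: 150 untreated regions, or 0.935 per Mb, and 18 PMA regions, or 0.112 per Mb. In the untreated lists without replicate 1, 2 or 3 the X held 16, 25 and 29 regions, or 0.0997 to 0.181 per Mb, on both sides of the PMA value. Regions per Mb depend on list length, and these lists are shorter than the PMA list, so the shares below are the fairer comparison. Of the 20 chromosomes, the X was the only one whose shares in the lists had separate 95% intervals, 1.498% (1.27 to 1.76) untreated and 0.69% (0.41 to 1.09) after PMA. In the reduced untreated lists the X held 1.06% to 1.26%, each above the PMA share, with intervals that overlap that of the PMA list. The separation thus did not hold when each list used 2 replicates. These intervals rest on only 16, 25 and 29 regions and are wide, so their overlap does not show that the gap closed.

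**Figure D3:**
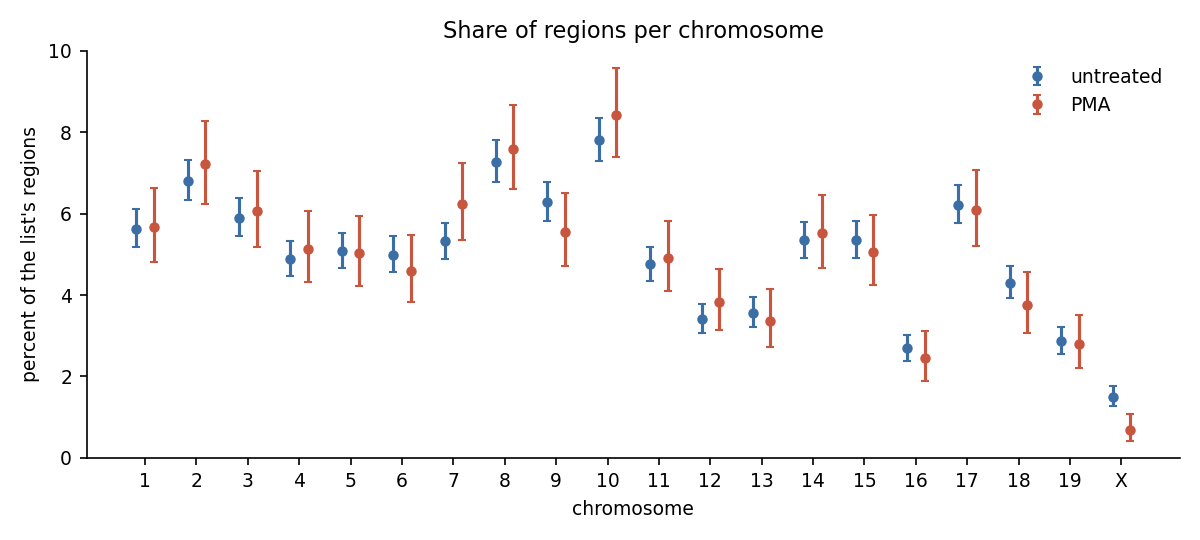
Percent of the regions of the untreated and of the PMA list on each chromosome, with exact 95% binomial intervals. Chromosome 10 is highest in both lists (7.81% and 8.43%), and the intervals of the lists are apart only on the X chromosome (1.498% and 0.69%).

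Regions lay in denser groups than uniform placement gave. Uniform placement follows neither transcribed stretches nor the splitting of an enriched stretch into several peaks. The tests below therefore cannot tell grouped binding from grouped transcripts. In untreated cells 6377 regions (63.7%, 62.7 to 64.6) had another region within 10 kb, against a mean of 8.81% when regions were placed at random on their chromosomes, and after PMA 1099 (42.1%, 40.2 to 44.0) against 2.47% (permutation of positions with 10000 placements, one-sided p = 0.0001 for both lists, the smallest these can give). Without untreated replicate 1, 2 or 3 the untreated share was 34.9%, 35.6% and 39.4%. This share depends on list length, and in lists of equal length by −log10 q it was 40.2% untreated and 42.1% after PMA. The fullest 1 Mb window of the untreated list held 68 regions between 69.9 and 70.8 Mb of chromosome 14 (69860968 to 70751196), where no random placement put more than 25 in any window. These regions had a median fold of 2.81, below that of the whole list, and 16 of them overlapped a PMA region. In the untreated lists without replicate 1, 2 or 3 the fullest window held 23, 28 and 28 regions, and at equal list length 30, against 22 in the PMA list. Next came chromosome 17 at 3080579 to 3532963 and at 12315954 to 13143785, with 61 regions each, chromosome 10 at 84177560 to 85119814 with 54, and chromosome 18 at 69552913 to 70203893 with 53. The PMA list had 13 to 19 regions in each of these 5 windows. Its own fullest windows were on chromosome 10 (38739990 to 39617090) with 22 regions, on chromosome 14 (26281179 to 26567498 and 69863794 to 70712461) and chromosome 7 (103702443 to 104533973) with 19 each, and on chromosome 1 (92896482 to 93892681) with 18. Each of these windows held 30 to 63 untreated regions. The chromosome 14 window near 70 Mb was among the fullest of both lists.

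**Figure D4:**
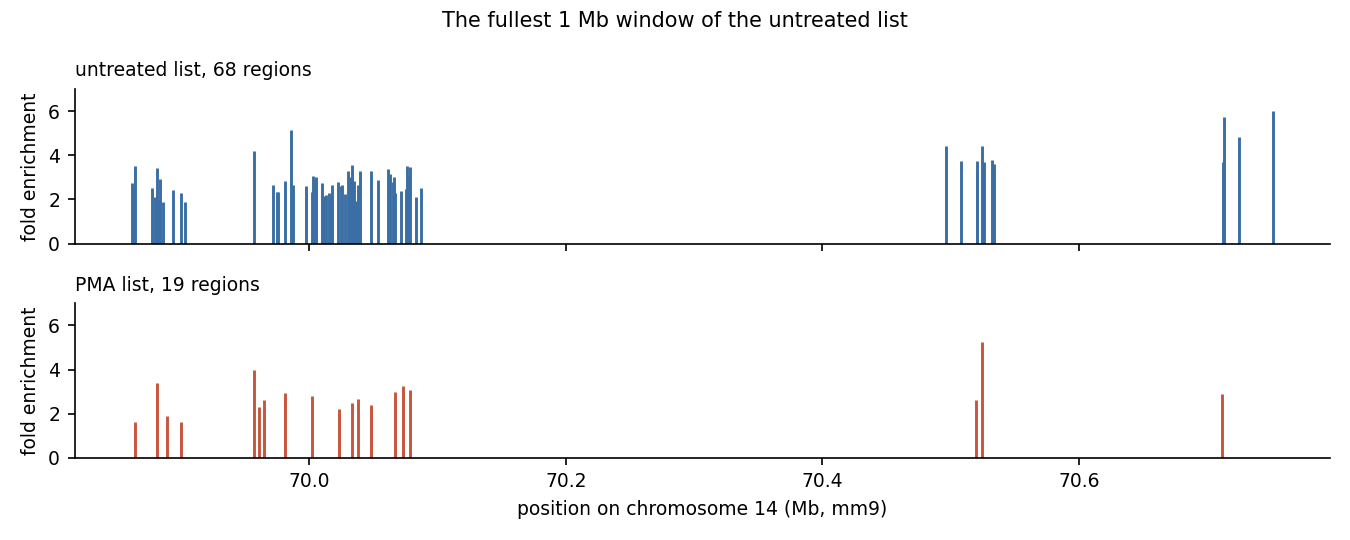
Regions in the fullest 1 Mb window of the untreated list, on chromosome 14 in mm9. Each vertical line is a region at its centre (x axis, Mb) with its fold enrichment of IP over input (y axis). The 68 untreated regions (upper) and 19 PMA regions (lower) are drawn on one scale.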

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

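The reduced untreated lists, the comparison of region centres and the list limited to regions with member peaks in all 3 replicates were chosen after seeing the data. Of 111 alternative values for 17 results, 84 kept their direction, their side of the threshold and, where untested, their size. These 84 include the alternatives with every row as deposited and with main chromosomes only. Both equal the main lists here, so their values could not differ. Overlap in both directions, local overlap and clustering kept their direction and side of the threshold under every alternative run, with the smallest p that 2000 placements can give (0.0005). The share of PMA regions with an untreated partner still ranged from 14.7% (lists of equal length by fold) to 63.1% (regions within 1 kb), and that of untreated regions from 6.05% (centres within 100 bp) to 34.1% (without replicate 1). The ratio of the overlap to that of locally moved PMA regions ranged from 3.02 (moves of 1 to 5 kb) to 37.2 (moves of 50 to 500 kb). Clustering kept its p, not its size: without 1 untreated replicate, 34.9% to 39.4% of untreated regions had a neighbour within 10 kb and the fullest window held 23 to 28. Leaving out 1 untreated replicate moved the number of untreated regions to between 1505 and 2367, their median width to between 746 and 826 bp (with bounds still joined over 3), their X share to between 1.06% and 1.26% and their chromosome 10 share to between 7.94% and 9.10%. These lists keep only regions with 3 member peaks from 2 replicates, by their construction. The higher fold of shared PMA regions was lost against all 3 (difference 0.0353 to 0.0719), and that of untreated regions lay between −0.0426 and 0.0181. With a mean −log10 q of at least −log10 of 0.001, 6358 untreated regions remained. Median widths were then 562.5 bp untreated and 844 bp after PMA, and the untreated X share was 1.12%. Merging within 1 kb gave an untreated width of 543 bp, and member peaks in all 3 replicates 521 bp. At equal list length by −log10 q, the untreated shares were 1.23% on X and 8.78% on chromosome 10. By base pairs covered, chromosome 10 held 8.57% of the full untreated list. The small untreated difference between shared and unshared regions (−0.03 by fold, permutation p = 0.494) reversed to 0.49 by −log10 q and 208 bp by width (permutation p = 5.0e-05 for both), and to 0.0353 with reciprocal overlap of 50%, within chance (permutation p = 0.393). No alternative that leaves out a PMA replicate was run, since 1 replicate alone would remain. No paired analysis was possible because the lists hold no values per replicate. Unknown depth limits every statement on a region missing from a list.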

Other observations

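The widest untreated regions, a group chosen after their values were seen, had low folds. They were an 8150 bp region on chromosome 17 (12947058 to 12955207) with a fold of 2.52, a 6007 bp region on chromosome 1 (92720241 to 92726247) at 2.06, regions of 5919 and 5366 bp on the X chromosome (100656636 to 100662554 and 100668938 to 100674303) at 1.63 and 1.69, and a 4734 bp region on chromosome 10 (119875904 to 119880637) at 1.75. The first and second overlapped PMA regions, with folds up to 3.12 and 1.98, and the other 3 did not. The widest PMA regions were on chromosome 18 (61820112 to 61824580, 4469 bp, fold 3.37) and chromosome 13 (56192852 to 56196936, 4085 bp, fold 5.36), and both had 2 untreated partners.

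In 1 Mb bins, the greatest surplus of the PMA list over all 3 reduced untreated lists was at 39 to 40 Mb of chromosome 10, with 18 regions against 8 to 11. The greatest deficit was at 119 to 120 Mb of the same chromosome, with 4 against 10 to 21. The full untreated list held 44 regions in the first of these bins and 32 in the second. The PMA list is longer than each reduced list, which by itself favours a surplus. These bins were picked for their values, and their differences are given as values only.

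The tests on list length and width below were chosen after the member peaks had been seen, and those on the X chromosome and on neighbourhoods before their results were seen. The PMA list had 2609 regions and the untreated list 10013, and PMA regions were wider. The raw number of peaks called in PMA replicates 2 and 3 does not account for the shorter list. Up to the last shared region 49502 and 92243 had been called in them, against 87282, 40750 and 33409 in the untreated replicates. At most 8.85% and 4.34% of them entered the PMA list, against at most 13.6%, 27.1% and 31.3% for untreated replicates 1, 2 and 3. Such counts do not tell how many called peaks recurred between replicates. For PMA replicate 1 the number called stays open: the list holds 0 member peaks of it, which does not tell how many were called. A candidate explanation of its length is that 3 member peaks drawn from 2 replicates were required in the PMA list: under that rule the untreated list held at most 2367 regions. Whether the rule also accounts for the width cannot be told: the lowest median width under it, 746 bp against 780 bp, is of regions with bounds joined over 3 replicates, and the 811 untreated regions joined from only 2 had 586 bp. Regions with 1 member peak in each untreated replicate had a PMA partner in 11.0% of cases (10.2 to 11.7), the other untreated regions in 26.1% (24.6 to 27.8). These kinds also differed in median width, 465 against 718.5 bp, and wider regions were shared more often, in place and when moved. No comparison at matched width was made, so the contrast cannot be assigned to member peaks or to width. Of the 100 untreated regions with the highest fold, 87 were of the first kind, which made up 7003 of all 10013. A PMA partner was present for 16 of these 100, against 15.5% of the whole untreated list. A loss or gain of HP1γ-bound RNA after PMA remains open, as untested: the lengths of these lists do not speak for either.

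The share of regions on the X chromosome was lower after PMA, 0.69% against 1.498%. Drawing 3 member peaks from 2 replicates lowered the untreated share to 1.06% at the least and 1.26% at the most, partly inside the PMA interval (0.41 to 1.09), and the 18 PMA regions on X are too few to decide whether it may account for all of the gap. Fewer peaks called on X is also undecided: PMA replicate 2 had 1.28% to 1.48% of its called peaks on X, below all untreated replicates (1.73%, 2.08% and 2.11% at the least), but PMA replicate 3 had 1.78% to 2.02%. Both of its limits lie above the 1.73% of untreated replicate 2, the lower one within counting error of it. By the values alone, PMA replicate 3 goes against a share below every untreated replicate in both PMA replicates. Its limits also lie below the 2.08% and 2.11% of the other untreated replicates. With 2 PMA and 3 untreated replicates, the spread between replicates leaves the question undecided, as does counting error. The X chromosome was singled out among 20 after their shares had been compared.

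The overlap of the lists could reflect only that both follow the same neighbourhoods, such as the same long transcribed stretches. Against this, PMA regions moved by 5 to 50 kb met an untreated region in at most 8.62% of cases, while 54.8% did so in place, and a move of only 1 to 5 kb left the overlap 3.02 times that of moved regions. A move can also carry a region off any transcribed stretch that is shorter than the move. Moves of 5 to 50 kb therefore cannot count against shared stretches of up to 50 kb. Moves of 1 to 5 kb cannot do so for stretches of up to 5 kb, so shared short stretches stay open. The mean share of moved regions with a partner was 18.2% for moves of 1 to 5 kb, 7.0% for 5 to 50 kb and 1.47% for 50 to 500 kb. What fixes the shared positions was not tested, as no sequence of the build was used. An effect of the input, or of stretches where reads of any RNA gather, stays open too, because input and IP values per library were not analysed here.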
